A study of Mus musculus with 6 samples.

How the data were processed

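Gene expression was measured with Affymetrix arrays in 4T1 cells, a mouse mammary carcinoma line, after treatment with the kinase inhibitor TKI258 or with its vehicle DMSO. Per the labels' protocols, 750000 cells were seeded per 10 cm dish in medium with 10% serum, grown for 24 h, and then kept for 16 h with 500 nM TKI258 or DMSO. RNA was taken from separate dishes, 3 per condition, and amplified and biotin-labelled before hybridisation, per the labels' protocols. The 6 arrays were grouped by their titles.

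The deposited values are 1 number per probe set and array for 35557 probe sets. RMA, affy and limma are named, without version, role or order, per the submitters' processing notes. The deposited values were taken to be log2 signals from their range and from the near-equal quartiles of the arrays, since the scale is not given in the sources used here. RMA as usually run subtracts background, sets all arrays to a common distribution and summarises the probes of a set, which shrinks the changes of dim probe sets and would hide a shift shared by all genes. Array medians lay between 4.97 and 5.04 log2 units. The table has no detection calls, so no gene could be called absent, and the number of arrays limits the precision. Chip control probes for RNA quality carry no recognisable name in the table, so the planned comparison of their 3 prime and 5 prime signals was not run.

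Probe sets were named through the platform annotation of 2016. Of the probe sets, 21789 had 1 gene symbol, 1621 had several and 12147 had none in that annotation. Only those with 1 symbol were used for genes. Gene IDs of 21698 of them were found in the reference gene table of assembly GRCm38.p6, used for names alone, and 0 symbols changed. Each gene was represented by its probe set with the highest mean over all 6 arrays, which gave 19938 genes, 999 of them with more than 1 probe set. In 141 of these some probe sets passed the threshold when tested singly and others did not, and in 0 did passing probe sets go both ways.

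TKI258 was compared with DMSO in limma 3.58.1 under R 4.3.3, with lmFit and eBayes on the log2 values and treatment as the only term. The p-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05, and no filter was applied. Log2 changes are TKI258 minus DMSO and are given with the standard error (SE) of limma's moderated fit, with n = 3 arrays per group. The 33 gene lists came from textbook knowledge and were tested with camera at a preset inter-gene correlation of 0.01, two-sided and adjusted over the 33 lists. Camera with an estimated correlation and fry, a rotation test of each list by itself, were alternatives. Lists overlap: cyclin D1, for example, belongs to 3 of them. The tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined.

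That rule took the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, leaving out clone and predicted names. It added up to 4 members per list with the smallest adjusted p, or 2 members where none passed, and a fixed set of FGF receptors, D cyclins, ERK feedback genes, Mmp9 and Birc5. It gave 137 genes. Other genes are named where a count of members was 5 or fewer, or in the closing observations, and those were chosen after their values were seen.

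The test was checked on simulated data for 19938 genes, made from the real means and fitted spread for TKI258 against DMSO. Of 50 genes changed at each size, 0 were recovered at a log2 change of 0.25, 36 at 0.5, 48 at 1 and 50 at 2, with 8 false calls among 142. With no change simulated there were 0 calls. The simulation with changes altered 200 genes, while 27% of genes passed in the real data, so its adjustment was stricter. The smallest log2 change past the threshold in the real data was 0.186, so recovery of small changes there is not given by this check. In a separate simulation of this comparison, lowering the DNA replication list by 0.3 was called downward by camera and 0 lists without shared genes were called. Genes were simulated independently of one another, so this could not show false list calls that come from correlation between genes.

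Alternatives were the replicate number as a block, each array left out in turn, renewed quantile normalization, median centring, a filter on genes with a mean above 5.00, the mean of a gene's probe sets, eBayes with trend and robust, array weights, an adjusted p of 0.01, a test without moderated variance, limma's treat against a fold of 1.2, and probe sets tested singly. Control probe sets could not be recognised by name, so this last alternative took all probe sets from the first ID in the annotation upward.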

Results

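The data were 6 Affymetrix arrays of 4T1 mouse mammary carcinoma cells, 3 from dishes given DMSO and 3 from dishes given 500 nM TKI258 for 16 h. TKI258, or dovitinib, inhibits the FGF, VEGF and PDGF receptor tyrosine kinases. The comparison asks which transcripts differ after the inhibitor. Correlations over all genes were 0.997 to 0.998 between arrays of a group and 0.988 to 0.990 between groups. The first principal component held 75.9% of the variance and separated the groups, with scores of -24.77 to -23.82 for DMSO and 23.63 to 25.39 for TKI258.

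After TKI258, most measured genes of the ERK pathway output, DNA replication, mitosis and ribosome biogenesis lists fell, while most of the interferon-response, lysosome and FOXO target lists rose. Camera called these 7 lists at the preset correlation and none with an estimated correlation, where the adjusted p was 0.0605 for ERK output, DNA replication, mitosis, interferon and FOXO, 0.0668 for ribosome biogenesis and 0.258 for lysosome. Of 19938 genes, 2866 were higher and 2519 lower in limma at an adjusted p below 0.05. With the arrays centred on their medians 2497 were higher and 2622 lower, so which direction held more genes depended on the scaling. At least 2-fold changes numbered 289 higher and 139 lower. Of the 5385 genes past the threshold, 5373 had groups that did not overlap. Over all genes the share without overlap was 40.2%, against 10% by chance. The median log2 change of all genes was 0.01.

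The largest rise was in Slc40a1, the iron exporter ferroportin, from 3.62 ± 0.25 (SD, n = 3) to 7.55 ± 0.24 log2 units, a log2 change of 3.94 (SE 0.14, adjusted p = 6.61e-07). Next came the chemokine gene Cxcl15 at 3.88, Gdpd2 at 3.64, the complement-activating proteases Masp1 at 3.27 and C1s1 at 3.23, and the acute-phase gene Saa3 at 3.12. The death receptor gene Fas rose by 3.00, Trp53inp1 by 2.99, Cbr2 by 2.89, Gbp2b by 2.80, the PDGF receptor ligand gene Pdgfc by 2.75 and Gbp3 by 2.66. The largest fall was in the cadherin gene Cdh17, from 8.12 ± 0.03 (SD, n = 3) to 4.59 ± 0.15, a log2 change of -3.54 (SE 0.08, adjusted p = 1.03e-07). Next were the stromelysin gene Mmp3 at -2.89, Il24 at -2.78, the proliferin gene Prl2c5 at -2.54, the collagenase gene Mmp1b at -2.48 and the E-selectin gene Sele at -2.30. Slc14a1 had a log2 change of -2.27, the uridine phosphorylase gene Upp1 of -2.26, the Notch pathway genes Nrarp and Dll4 of -2.17 and -2.11, the ETS factor gene Etv4 of -2.09 and Fam110c of -2.08. Mmp1b, Gbp2b, Gbp3, C1s1 and Prl2c5 have close relatives in the genome, so their probes may read more than 1 gene. In 8 of these 24 genes (Slc40a1, Cxcl15, Gbp2b, Gbp3, Cdh17, Il24, Mmp1b and Sele) the dimmer group's mean lay below the median of all probe sets, where a log2 change is less certain.

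**Figure D1:**
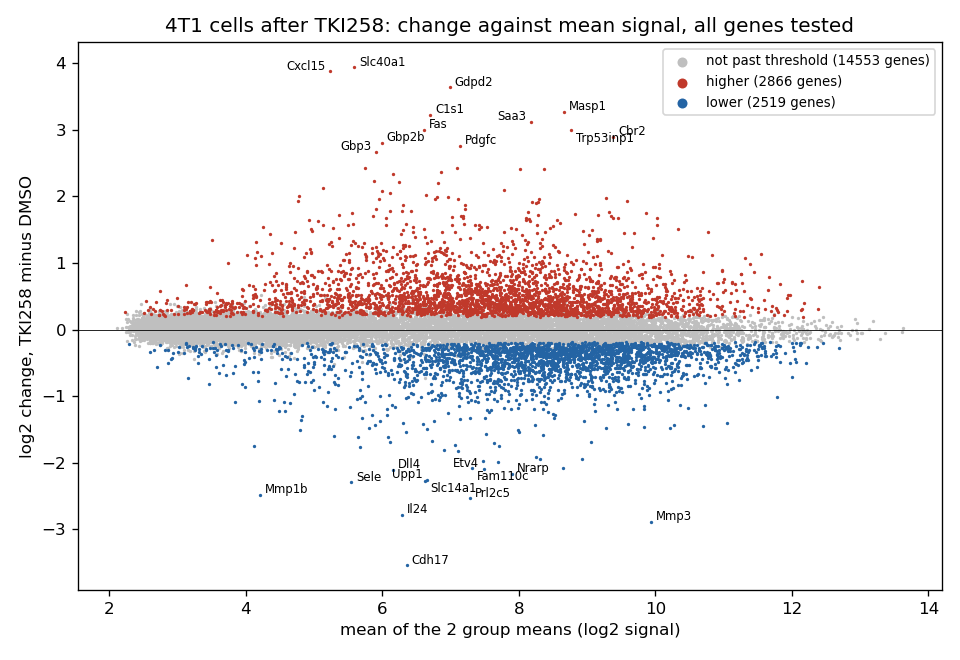
Log2 change of each of 19938 genes (TKI258 minus DMSO, vertical axis) against the mean of its group means in log2 units (horizontal axis), each dot 1 gene. Red dots are the 2866 genes higher, blue dots the 2519 lower and grey dots the 14553 not past the threshold, and the 24 largest named changes are labelled.

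ERK pathway output, the genes that MAP kinase signalling induces, fell most of all lists by median, at a log2 change of -0.81. Of 32 measured members 25 fell, 2 rose and 5 did not pass, and adjusted over the list alone 26 fell and 2 rose. The EGF receptor ligand gene Hbegf fell by 1.95 (SE 0.07, adjusted p = 6.43e-07), with the ETS factor genes Etv4 and Etv5 at -2.09 and -1.94 and the urokinase receptor gene Plaur at -1.69. The feedback inhibitor genes Spry4, Dusp6 and Spry2 also fell, at -1.43, -1.06 and -0.41. The members that rose were Rcan1 at 0.54 and Fos at 0.47. Camera gave an adjusted p of 2e-15, and the adjusted p was 0.0605 with an estimated correlation.

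Of the 13 receptor kinase genes that TKI258 targets, 2 rose and 0 fell, with the same counts adjusted over the list alone. Pdgfra rose by 1.5 (SE 0.07, adjusted p = 1.53e-06) and Fgfr1 by 0.30 (SE 0.06, adjusted p = 0.00428). Fgfr2 had a log2 change of 0.20 (adjusted p = 0.0761), Fgfr3 of 0.05 and Fgfr4 of -0.01, and these did not pass. The list was not called by camera (adjusted p = 0.18). Among 22 FGF ligand and co-receptor genes, 3 rose, namely Fgf7 at 0.59, Fgfrl1 at 0.53 and Fgf1 at 0.42. Sdc4 alone fell, by 0.19 (adjusted p = 0.04996), and the counts adjusted over the list alone were 3 and 0. The call of Sdc4 was lost in 9 alternatives, among them each array left out except TKI258 replicate 3, with adjusted p from 0.00111 to 0.304 over its 13 alternatives. Camera did not call this list (adjusted p = 0.416).

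Of 45 DNA replication genes 42 fell and 0 rose (43 and 0 adjusted over the list alone), with Orc1, an origin recognition subunit, at -1.15 (SE 0.07, adjusted p = 8.24e-06), Tk1 at -0.86 and Mcm10 at -0.80. E2f2, Gins2 and E2f1 did not pass, at -0.32, -0.08 and -0.01. By camera the adjusted p was 2.21e-23, and the adjusted p was 0.0605 with an estimated correlation. Of 47 mitosis genes 38 fell and 0 rose (40 and 0 adjusted over the list alone), among them Mybl2 at -1.24, Espl1 at -0.61, Birc5 (survivin) at -0.54 and Aurka at -0.49. Here camera gave an adjusted p of 1.99e-16, with an adjusted p of 0.0605 under an estimated correlation. Of 9 G1 cyclin and CDK genes 7 fell and 0 rose, also adjusted over the list alone, with Ccne2 at -1.19, cyclin D1 gene Ccnd1 at -1.02, Ccne1 at -0.93 and Ccnd3 at -0.27. Ccnd2 and Cdk4 did not pass, both at 0.13. The camera adjusted p was 0.000134, and the adjusted p was 0.0668 with an estimated correlation. Among 6 CDK inhibitor genes Cdkn2c rose by 0.41 and Cdkn1b, which encodes p27, by 0.40, and 0 fell, as they did adjusted over the list alone (camera adjusted p = 0.211).

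MYC targets and ribosome biogenesis genes fell in 36 of 38 cases and rose in 0, the same adjusted over the list alone. Odc1, the rate-limiting enzyme of polyamine synthesis, fell by 1.41 (SE 0.07, adjusted p = 1.84e-06), the RNA polymerase I subunit gene Polr1b by 1.11, and Ndufaf4 and the dyskerin gene Dkc1 had -0.97 and -0.96. Cdk4 and Polr1c did not pass. The adjusted p from camera was 2.16e-24, and the adjusted p was 0.0668 with an estimated correlation.

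FOXO targets rose in 18 of 28 cases and fell in 1, Ccnd1, with the same counts adjusted over the list alone. The list did not separate induced from repressed targets, and Ccnd1 is also a member of the ERK output list. Its fall can therefore not be read as going against FOXO output. Trp53inp1 rose by 2.99 (SE 0.06, adjusted p = 7.43e-08), Sesn3 by 1.92, Klhl24 by 1.67 and the muscle atrophy ubiquitin ligase gene Fbxo32 by 1.59. The camera adjusted p was 3.39e-10, and the adjusted p was 0.0605 with an estimated correlation. Of 20 p53 targets 6 rose and 4 fell, also adjusted over the list alone, and camera did not call them (adjusted p = 0.15). Fas, Trp53inp1, Perp at 1.10 and Sesn1 at 0.98 were among those higher, while Aen at -0.74, Tnfrsf10b at -0.55, Polk at -0.37 and Mdm2 at -0.21 were lower. Of 20 BCL2 family and IAP genes 6 rose and 3 fell, also adjusted over the list alone, without a camera call (adjusted p = 0.211). The BH3-only gene Bmf rose by 1.54, Birc2 by 0.79 and Birc3 by 0.63, while Birc5, Bok and Bcl2l1 fell.

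**Figure D2:**
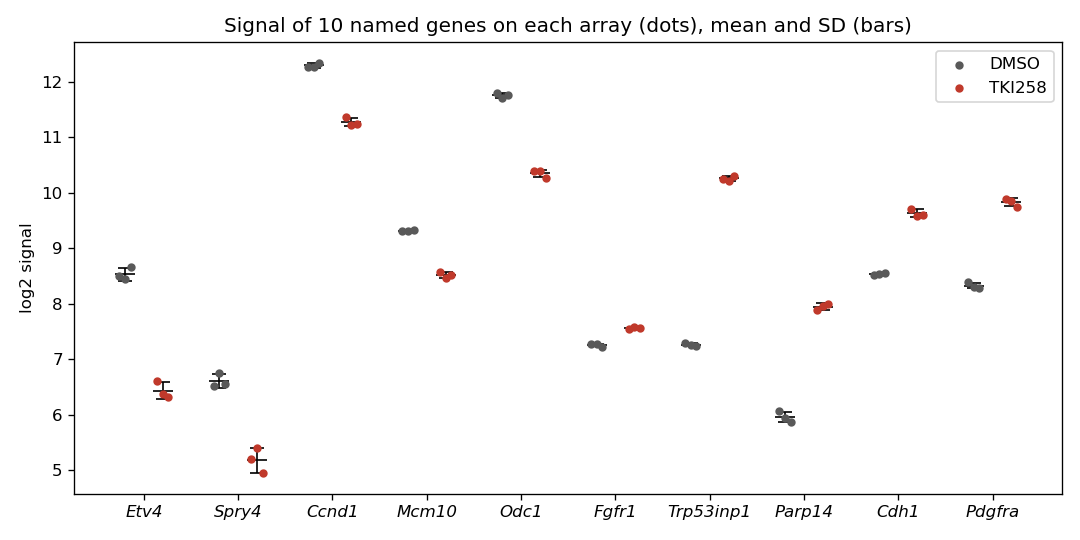
Log2 signal (vertical axis) of 10 named genes in each array, with 3 DMSO arrays in grey and 3 TKI258 arrays in red; horizontal bars give the mean and whiskers the SD. The groups do not overlap for any of the 10, from Etv4, with a log2 change of -2.09, to Trp53inp1, at 2.99.

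Interferon-response genes rose in 29 of 38 cases and fell in 0 (31 and 0 adjusted over the list alone), with a median log2 change of 0.83. Gbp3 rose by 2.66, Parp14 by 1.99 (SE 0.07, adjusted p = 6.43e-07), Rtp4 by 1.88 and the antigen-loading gene Tapbp by 1.5. Camera gave an adjusted p of 4.79e-16, and the adjusted p was 0.0605 with an estimated correlation. NF-kB cytokine genes went both ways, with 14 of 30 higher and 6 lower (16 and 8 adjusted over the list alone). Saa3 rose by 3.12, the neutrophil chemokine gene Cxcl5 by 1.13 and the NF-kB inhibitor gene Nfkbie by 0.87, while Csf3, which encodes G-CSF, fell by 1.33. The camera adjusted p was 0.0366, and the adjusted p was 0.315 with an estimated correlation. That call was also lost without DMSO replicate 1, DMSO replicate 2 or TKI258 replicate 2, at adjusted p of 0.0521, 0.0601 and 0.0612, over a range of 0.018 to 0.0612 in 14 alternatives.

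Few markers of other cells passed beside these immune genes. Of 12 macrophage markers, Cd68 rose by 0.82, while Cd53 fell by 1.76 and Fcer1g by 0.33. Of 7 lymphocyte markers and 7 adipocyte markers 0 passed in limma, with Cd79a at -0.16, Cd3g at 0.15, Adipoq at 0.16 and Plin1 at 0.13. Of 10 endothelial markers Eng rose by 0.43. Counts adjusted over the list alone were the same in these 4 lists, and camera gave adjusted p of 0.735, 0.94, 0.693 and 0.94 for macrophages, lymphocytes, adipocytes and endothelium. Of 11 fibroblast markers the proteoglycan gene Dcn rose by 2.01 and Pdgfra by 1.5, and the other 9 did not pass, also adjusted over the list alone. Camera called this list upward (adjusted p = 0.0366), but with adjusted p of 0.327 under an estimated correlation. The call was lost in 6 of 14 alternatives, including without DMSO replicate 2 and without TKI258 replicate 1 (adjusted p = 0.0601 and 0.0900), over a range of 0.0244 to 0.192.

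Lysosome and autophagy genes rose in 23 of 30 cases and fell in 1, Ctsl at -0.27 (25 and 1 adjusted over the list alone). Gpnmb rose by 1.12 (SE 0.06, adjusted p = 4.46e-06), the proton pump subunit gene Atp6v0d1 by 1.02, the cathepsin D gene Ctsd by 0.84 and the autophagosome gene Map1lc3b by 0.78. By camera the adjusted p was 6.94e-11, and the adjusted p was 0.258 with an estimated correlation. Cholesterol synthesis genes rose in 7 of 20 cases and fell in 0 (8 and 0 adjusted over the list alone), with Tm7sf2 at 0.86, Ebp at 0.69, Mvd at 0.59 and Hmgcs1 at 0.46. Their camera adjusted p was 0.0142, and the adjusted p was 0.585 with an estimated correlation. Without TKI258 replicate 1 it was 0.0900, in a range of 0.000507 to 0.0900 over 14 alternatives. Fry did not call the cholesterol list (adjusted p = 0.0622). Of 14 fatty acid synthesis genes 5 rose (Acss2 at 0.63, Lpin1 at 0.50, Scd1 at 0.41, Scd2 at 0.40 and Fads1 at 0.25) and Elovl5 fell by 0.22, also adjusted over the list alone. Their camera adjusted p was 0.0338, and the adjusted p was 0.581 with an estimated correlation. It was 0.0601 without DMSO replicate 2, 0.132 without TKI258 replicate 1 and 0.0705 without dim genes, in a range of 0.0036 to 0.132.

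Unfolded protein response genes fell in 10 of 18 cases and rose in 1, Sel1l at 0.24 (11 and 2 adjusted over the list alone). The chaperone gene Hyou1 fell by 0.66 (SE 0.06, adjusted p = 8.40e-05), Creld2 by 0.52, Edem1 by 0.44 and Manf by 0.40. The camera adjusted p was 0.00419, and the adjusted p was 0.108 with an estimated correlation. ATF4 and amino acid response genes split into 6 higher and 11 lower of 30 (7 and 13 adjusted over the list alone), with Nupr1 at 1.01, the cystathionine lyase gene Cth at -1.12, Shmt2 at -0.67 and Slc7a11 at -0.65. Glycolysis and hypoxia genes split into 6 higher and 10 lower of 29, also adjusted over the list alone, with Aldoc at 1.71, Ndrg1 at 0.62, the carbonic anhydrase gene Car12 at -1.32 and Egln3 at -0.75. Camera called neither (adjusted p = 0.151 and 0.15).

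Epithelial markers rose in 15 of 32 cases and fell in 3 (17 and 3 adjusted over the list alone). The E-cadherin gene Cdh1 rose by 1.09 (SE 0.06, adjusted p = 5.58e-06), the matriptase gene St14 by 0.97, the plakoglobin gene Jup by 0.91 and the claudin gene Cldn4 by 0.89, while Krt18, Krt7 and Ovol1 fell by 0.50, 0.39 and 0.21. The camera adjusted p was 0.00419, and the adjusted p was 0.315 with an estimated correlation. Of 25 mesenchymal markers 5 rose and 3 fell, also adjusted over the list alone. Sparc rose by 0.87, Fn1 by 0.51, Acta2 by 0.51, Col5a1 by 0.31 and Tgfbi by 0.29, while Twist1, Itga5 and Tnc fell by 0.52, 0.47 and 0.44. That list was not called by camera (adjusted p = 0.425).

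TGF-beta and BMP response genes rose in 11 of 19 cases and fell in 1, Tgfb1 at -0.57 (11 and 2 adjusted over the list alone). Ltbp2 rose by 1.77, the ligand gene Tgfb3 by 1.45 (SE 0.06, adjusted p = 1.43e-06), and the differentiation inhibitor genes Id3 and Id2 by 1.42 and 1.12. The adjusted p from camera was 0.000151, and the adjusted p was 0.0976 with an estimated correlation. Of 24 SRF and YAP targets 8 rose and 3 fell (9 and 3 adjusted over the list alone), with Amotl2 at 0.69, Tpm1 at 0.59, Ajuba at 0.57, Fhl2 at -0.999, Srf at -0.35 and Axl at -0.24. Camera did not call them (adjusted p = 0.0952).

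Matrix protease and inhibitor genes went both ways, with 7 of 21 higher and 10 lower (9 and 10 adjusted over the list alone) and no camera call (adjusted p = 0.168). Mmp3 fell by 2.89, Plaur by 1.69, the gelatinase B gene Mmp9 by 1.44 (SE 0.09, adjusted p = 8.06e-06) and the protease inhibitor gene Timp1 by 1.38, while Mmp11 rose by 1.35. Of 15 mammary differentiation genes 6 rose and 3 fell, also adjusted over the list alone. Stat5a rose by 1.10, Gata3 by 0.58 and Muc1 by 0.57, while the kappa-casein gene Csn3 fell by 1.30, Tfap2c by 0.30 and Cited1 by 0.23 (camera adjusted p = 0.425).

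Among 7 AhR targets Cyp1b1 rose by 1.67 (SE 0.07, adjusted p = 1.30e-06) and Aldh3a1 by 1.10, while Tiparp fell by 0.32. Of 18 NRF2 targets Gstm1 rose by 1.46, Hmox1 by 0.70, Gsta4 by 0.59 and Cbr1 by 0.31, while Slc7a11, Gclc and Srxn1 fell by 0.65, 0.47 and 0.21. Adjusted over the list alone the AhR counts were the same, and the NRF2 counts were 4 and 4. Camera called neither (adjusted p = 0.15 and 0.693). Of 11 housekeeping genes Hprt fell by 0.43 (adjusted p = 0.00173) and Tbp by 0.28 (adjusted p = 0.0187), and 9 did not pass, also adjusted over the list alone (camera adjusted p = 0.164). The call of Tbp was lost without DMSO replicate 1, DMSO replicate 2, TKI258 replicate 1 or TKI258 replicate 2, with adjusted p from 0.00383 to 0.0742 over 13 alternatives.

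**Figure D3:**
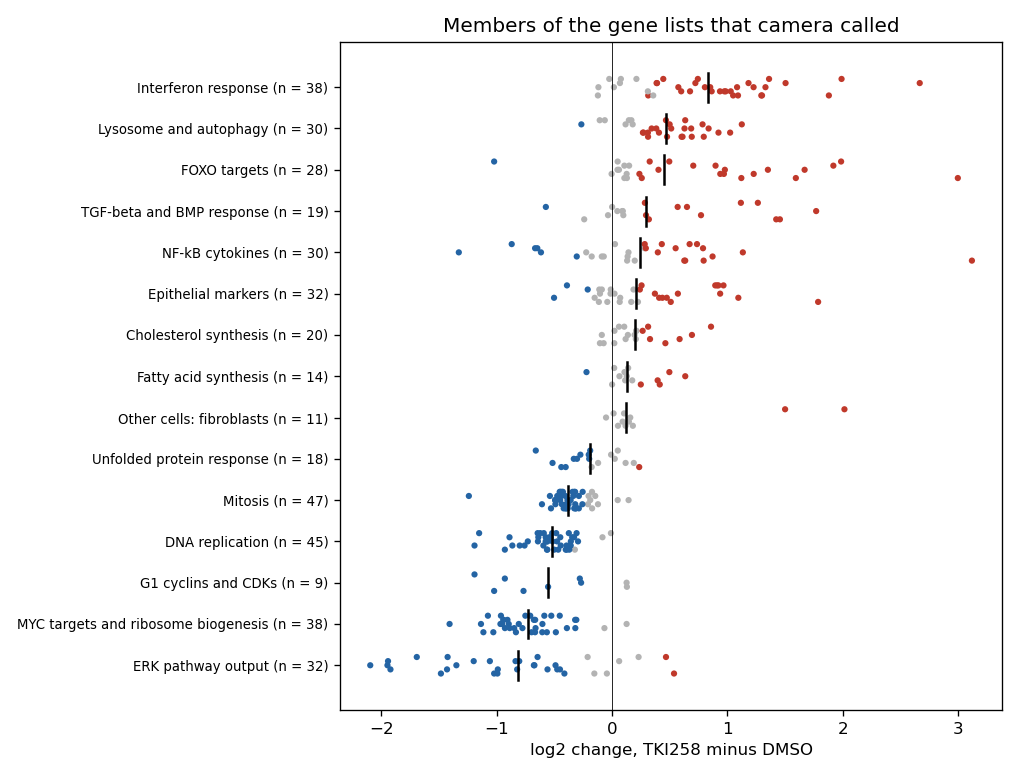
Log2 change (TKI258 minus DMSO, horizontal axis) of each member of the 15 lists that camera called at the preset correlation, with 1 dot per gene and a black bar at the list's median. Red members were higher, blue lower and grey not past the threshold; medians run from -0.81 for ERK pathway output to 0.83 for interferon response.

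Of the 33 lists camera called 9 upward and 6 downward, and 0 with an estimated correlation. There the residuals of only 4 degrees of freedom set the correlation. The test is also judged on these 4, so small p-values are hard to reach. Fry, which tests each list by itself and in which the other genes play no part, called 27. Cholesterol synthesis was the only list called by camera that fry left out.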

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

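The test of macrophage and lymphocyte markers was chosen after the result was seen. Probe sets outside the gene-level comparison also differed between TKI258 and DMSO when tested singly in limma. Of 5529 probe sets with no gene symbol and an ID above the first listed one, 428 passed, 133 higher and 295 lower. Of 6618 with an ID below it, 453 passed, 237 higher and 216 lower. Chip controls could not be recognised by name, and how many of these 6618 are controls rather than gene probes is unknown. Of 1621 with several symbols, 172 passed, 76 higher and 96 lower. These were singled out because a signal above the DMSO arrays, or below it, lay in data the comparisons did not use. The share that passed was 7.74%, 6.84% and 10.6% in these 3 sets, against 20.9% of probe sets with 1 symbol. Among probe sets with 1 symbol, 48.1% of the calls were lower, against 68.9% among the unnamed ones with higher IDs. That difference was not tested.

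The real grouping gave 5385 genes past the threshold, and of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many, the real one. The highest of the other splits gave 0. With 10 splits no share under 0.05 can be reached.

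Interferon-response genes rose. The titles name 4T1 cells alone, so the design gives no source of immune-cell RNA in the TKI258 dishes. Markers of such cells were checked nonetheless. The 19 measured macrophage and lymphocyte markers had a median log2 change of 0.029, against 0.827 in the interferon list. Resampling the markers gave a 95% bootstrap interval of -0.0481 to 0.0699, which is a spread among markers and not among dishes. These values argue against RNA of these cells as the source of the whole rise. Cd68 and Cd53 went opposite ways, at 0.82 and -1.76, and the other 17 markers lay below the median of all probe sets in both groups. A rise from such a level can register but was rare. Of 4899 genes at or below the markers' median DMSO mean of 3.77, 20 passed with a log2 change of at least 0.5. The largest was 3.94. Over all 19938 genes 2866 were higher, at any size of change. A small amount of RNA of macrophages or lymphocytes could therefore go unseen. Induced interferon stays open: among 16 interferon genes the largest change was 0.487 in Ifnz (adjusted p = 0.00113), with an upper bound of 0.656, and 0 others passed in limma. Most of the others had DMSO means below the array medians, such as Ifnb1 at 3.22 and Ifng at 3.52, where a small rise may go unseen. A direct effect of TKI258 on the interferon-response genes was not tested apart from induced interferon.

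More genes rose than fell at least 2-fold, at a ratio of 2.08. The ratio was 1.91 after renewed quantile normalization and 1.82 after median centring. The deposited arrays already had near-equal medians, from 4.97 to 5.04, so these steps could change little. They do not decide on scaling between arrays within RMA. A floor that cuts short the falls of dim genes is argued against as the whole cause. Among 5455 genes with a mean of 8 or more the ratio was 1.96 (90 against 46, exact 95% interval 1.36 to 2.86). That interval takes genes as independent of one another and does not cover the spread between dishes. The ratio may reflect the treatment, as a hypothesis, but RMA itself could not be undone here.

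Genes of DNA replication, mitosis and ribosome biogenesis fell, and they are bright, so a trend of the change with brightness could contribute. Of 10000 random lists matched on mean expression, 0 had a median as low as any of the 3 lists. The medians were -0.52, -0.38 and -0.73, and the matched lists lay around -0.03, -0.05 and -0.04. This argues against the trend as the cause. A change in the share of cells in each cycle phase and lower transcription per cell were not tested.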

How the results depend on the processing

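The removal of a loess trend of the change on brightness was chosen after seeing the data. Except for treat, given below, counts of genes higher and lower, in all and at least 2-fold, stayed within 1.5 times the reported ones under every alternative run, although median centring turned the balance to 2497 higher and 2622 lower. Leaving out each array gave 2289 to 2705 higher, 2026 to 2586 lower, 272 to 315 at least 2-fold higher and 128 to 155 at least 2-fold lower, and 3860 genes passed in all of these fits and in the full one. Lists called upward then numbered 6 to 9 and downward 6. The replicate numbers paired the arrays weakly at most: deviations of same-numbered arrays correlated at 0.0181, 0.0501 and 0.151 for replicates 1, 2 and 3. Between different numbers across groups the highest was 0.0727, so replicate 3 alone lay above it. Of 6 arrays, 3 correlated best with their own number. With the replicate block 2877 genes were higher and 2487 lower, 289 and 139 at least 2-fold, 9 lists were called upward and 6 downward, and 5085 of the 5385 calls were shared. Treat against a fold of 1.2 called 1057 genes higher and 864 lower, because it asks for a smaller change than 2-fold. Camera with an estimated correlation called 0 lists upward and 0 downward. In that setting its p-values rest on the 4 residual degrees of freedom, which makes small ones hard to reach. This limit and correlation between genes were not told apart as reasons for the lost calls. Fry, which sets no list against other genes, called 18 upward, and the cause of this difference was not tested. Of the 15 lists called, 11 were called in all 14 alternatives with the preset correlation. SRF and YAP targets and Mammary differentiation, not called, each passed in 1 of these 14, with the brightness trend removed (adjusted p = 0.0441, range to 0.188) and without dim genes (0.046, range to 0.687). Of 129 named genes past the threshold, 127 passed with the same sign in all 13 alternatives, and the exceptions were Sdc4 and Tbp. Fgfr2 and Ccnd2, not called, passed in 5 and 2 of them. No called list and no called named gene changed direction. The table holds no background signal, so which dim genes were detected is unknown.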

Other observations

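The 7 lists of this part were chosen after the data were first seen, and the tests of small nucleolar RNAs, protocadherins, complement genes, EGF family ligands and oxidative phosphorylation were chosen after some of their members' values were seen. Small nucleolar RNAs, which guide the modification of ribosomal RNA, fell in 34 of 51 cases and rose in 0. Snord42b fell by 1.06, Snord52 by 1.00 and Snord87 by 0.94 (adjusted p = 0.000314, 0.000937 and 0.00162 in limma). A fall together with ribosome biogenesis is a hypothesis: camera gave an adjusted p of 7.35e-12 over the 7 lists, but the adjusted p was 0.323 with an estimated correlation, so it stays open. Many of these RNAs lie in introns of host genes, and signal from host transcripts was not tested. Ribosomal protein genes did not follow: 3 of 55 fell (Rpl12 at -0.91, Rpl30 at -0.36 and Rps13 at -0.21), 0 rose, and the median log2 change was -0.01 (camera adjusted p = 0.392).

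Clustered protocadherin beta genes, neighbouring adhesion genes, rose in 9 of 22 cases and fell in 0. Pcdhb17 rose by 1.22, Pcdhb16 by 1.04 and Pcdhb19 by 1.00. The camera adjusted p was 0.00214, and the adjusted p was 0.137 with an estimated correlation. These genes are similar in sequence, so their probes are uncertain, and the list was picked because members rose. Of 8 EGF family ligand genes, the neuregulin genes Nrg1 and Nrg4 included, Hbegf, Btc and Tgfa fell by 1.95, 1.49 and 1.18 and 0 rose. Camera gave an adjusted p of 0.0245, which was 0.2 as an adjusted p with an estimated correlation, while the median was -0.02, since the other 5 did not pass. Of those, Ereg, Egf, Epgn and Nrg4 had DMSO means of 3.24, 4.83, 3.95 and 3.23, below the array medians, so a fall in them may not be readable. Nrg1, at 6.75, changed by 0.01. This list keeps the members whose falls prompted it, so its camera p is no independent support. Areg, another ligand of the EGF receptor, was not among the genes tested.

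Other hypotheses were not borne out as group changes. Beside Dll4 and Nrarp, of 11 Notch pathway genes Hes1 fell by 0.71, while Lfng rose by 0.73 and Jag1 by 0.28 (camera adjusted p = 0.479), so members moved both ways and lower Notch output stays open. Of 30 complement genes other than those seen first, Clu rose by 1.10, Cfb by 0.91, Serping1 by 0.63, C4b by 0.45 and Cfp by 0.29, while C1qbp, a mitochondrial protein despite its name, fell by 0.71 (camera adjusted p = 0.378). Of 101 oxidative phosphorylation genes taken by symbol prefix, assembly factors included, 8 rose and 10 fell (camera adjusted p = 0.479).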
